A study of Homo sapiens with 7 samples.

How the data were processed

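The material was SH-SY5Y, a human neuroblastoma line with a sympathetic, catecholamine-producing character. Cells carried a lentiviral short hairpin RNA against TDP-43, the RNA- and DNA-binding protein encoded by TARDBP, or a control hairpin, and were kept under puromycin as stable lines. The assay was hMe-Seal (5hmC-Seal), in which a glucosyltransferase places an azide-bearing glucose on 5-hydroxymethylcytosine (5hmC), a biotin is attached to it, and the labelled DNA fragments are pulled down and sequenced. There were 3 control and 3 knockdown libraries, and peaks were called per library, so that each has a list of its own. The input library of the series was not used here. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

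Per the submitters' processing notes, the build was hg38 and the tools were Bowtie2 2.4.4, SAMtools and MACS2 2.2.6, with no role or order given for them. Each deposited list gives, for every peak, a position, a summit, a score, a fold enrichment, a −log10 p-value and a −log10 q-value. The score, fold, p-value and q-value of a peak are the authors' own values and, apart from the relative depth described next, were used only to describe or rank peaks within a list. In every deposited list the smallest −log10 q-value was 1.30 or 1.31. Read totals per library are not given in the sources used here, so no counting interval was computed. A relative depth was instead read from the deposited values. The most frequent pairs of fold and −log10 p-value in each list were matched to a Poisson tail, which gives the background in reads per position. All of the 60 most frequent pairs matched in each list, within 0.002 on the −log10 scale (0.01 for control 2, too few of whose pairs matched whole reads, so that its reads were taken as scaled by 0.654, a factor inferred from the steps between its fold values). That background was 2.48, 7.29 and 2.85 in controls 1 to 3 and 2.27, 1.65 and 2.24 in knockdowns 1 to 3. The background rests on how MACS2 computes fold and p, which the sources used here do not spell out. They also do not say whether the input library served as the control for peak calling. If it did, the background may reflect the depth of that control where the pulldown was scaled to it, so it is an uncertain measure of a library's own depth, most of all for control 2.

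Everything else was computed here from the peak positions, on chromosomes 1 to 22 and X. Gene positions and biotypes came from a RefSeq gene table of assembly GRCh38.p14, the same build. The table has no strand, exons or sequence. Peaks were therefore placed in protein-coding genes, lncRNA genes or outside both. Promoter peaks, exon and untranslated features, and the repeat and CpG content of peaks were not analysed here. For the coverage of genes, peaks in overlapping genes count for each gene. For the shares of peak summits, a summit in both kinds of gene was counted as protein-coding only.

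Merged regions were the union of the 6 lists, with overlapping or adjoining peaks joined. A region was group-specific if 3 of 3 libraries of a group had a peak and 0 of 3 of the other did. Absence of a called peak is not absence of 5hmC. Overlap between lists was the base-pair Jaccard index. Gene-body coverage was the percent of a gene covered by peaks, for 16814 protein-coding genes of at least 5 kb. The 10077 genes with a mean of at least 1% were tested as log2(percent + 1), after each library's median deviation was removed. Differences are thus on the log2(percent + 1) scale, which understates changes of sparsely covered genes. Windows of 100 kb were tested in the same manner (17510 of 30295). Tests used limma 3.58.1 with a variance trend in R 4.3.3 and Benjamini-Hochberg adjustment at 0.05. Single values were compared with two-sided exact permutation tests over the 10 splits of the 6 libraries, whose smallest p is 0.1. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and bedtools 2.31.1.

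The test was tested on simulated data: lists in which the libraries of each region were reassigned at random, with changes planted in randomly drawn genes (10048 genes tested). A change was planted by dropping whole regions, drawn at random, from all 3 libraries of a group, more of them at a higher fold. A gene with few regions could thus lose all or none, so recovery does not measure sensitivity to an even change of that fold. The test recovered 27.1% of 48 genes planted at 1.5-fold, 32.6% of 46 at 2-fold, 54.8% of 42 at 4-fold and 63.6% of 44 at 8-fold, with 78 of 79 recovered genes in the planted direction. It also called 21 genes that overlap a changed gene and 21 other genes without a planted change. In 20 simulations without planted changes it called a median of 9 genes (2 to 17). Each of these made calls, so the adjusted p was not a reliable bound on false calls there. Regions were reassigned independently, so trends of a library with gene density or length were not simulated.

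The tests, thresholds, alternatives and naming rule were chosen before the data were examined, as were 18 gene lists: 5hmC and 5mC machinery, R-loop resolution, ALS and FTD genes, TDP-43 cryptic splicing targets, long synaptic genes, axon guidance, noradrenergic and mesenchymal neuroblastoma markers, embryonic kidney 293T markers (the packaging cells), glial and Schwann markers, DNA repair, transposable element silencing, innate immune sensing, splicing factors, ribosomal protein genes, HOX genes, autophagy and lysosome, and Wnt signalling. Lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. The naming rule took up to 12 called genes per direction with the largest log2 difference and no overlap of the groups. It added up to 4 members of smallest p per list, TARDBP, TET1, TET2 and TET3, and the 3 longest group-specific regions per direction. A gene that this rule takes is not reported here. Called genes with peaks in both groups, called windows and the genes with most group-specific regions were named in addition, after their values were seen. List levels were set against 10000 random lists of matched gene length, a comparison that was not in the plan made before the data were examined. Alternatives were a stricter peak threshold (−log10 q-value of 5), equal numbers of peaks (117949, those of smallest p), other pseudocounts, scalings, filters and units, each library left out in turn, and the replicate number as a block. A correction for gene density within 500 kb and gene length was added after seeing the data.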

Results

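The series asked how stable loss of TDP-43 alters the 5hmC landscape of SH-SY5Y cells. The data were 6 peak lists, 3 from control and 3 from knockdown cells, with 117949, 157157 and 126966 peaks in controls 1 to 3 and 142605, 119820 and 130412 in knockdowns 1 to 3. The background implied by the authors' fold and p-values, an uncertain measure of relative depth, was higher in every control list (2.48 to 7.29 reads per position) than in any knockdown list (1.65 to 2.27). Its means were 4.21 ± 2.68 and 2.06 ± 0.349 (SD, n = 3 each, ratio 0.488, exact permutation p = 0.1, the smallest that 3 against 3 allow). The ratio was 0.771 without control 2 and 0.610 without the rescaling of that library's values.

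**Figure D1:**
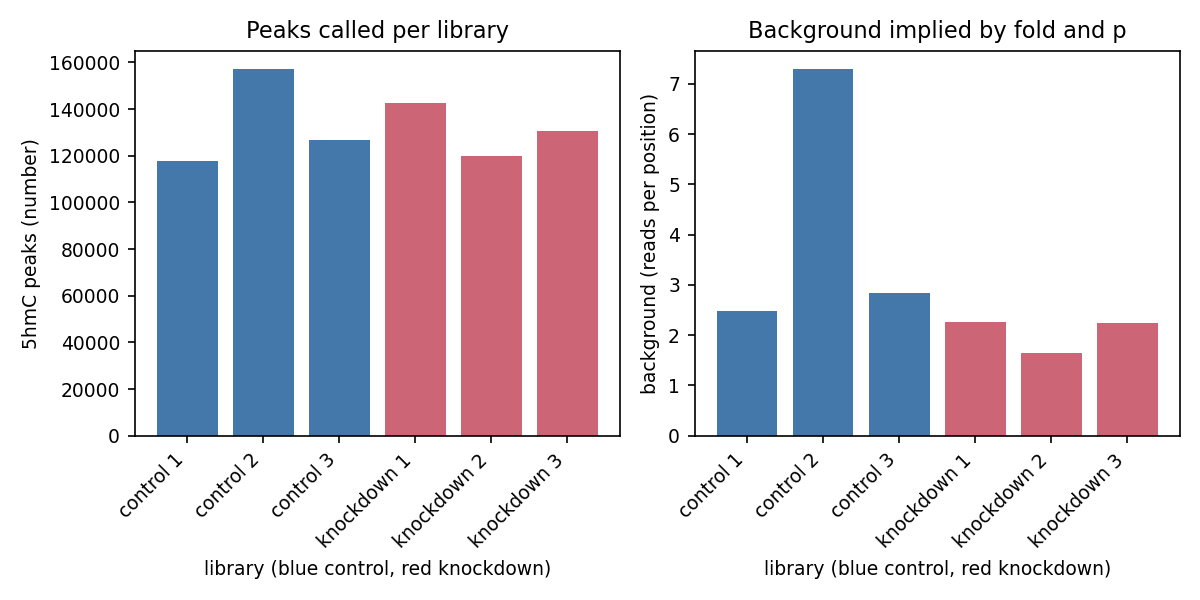
Peaks on chromosomes 1 to 22 and X (left, number) and background implied by the authors' fold and p-values (right, reads per position) for each of the 6 libraries, with bars from 0. Peak numbers of the groups overlap, while all 3 control backgrounds lie above those of the knockdown libraries.

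TARDBP, the targeted gene, spans 11012654 to 11030528 on chromosome 1 (hg38), and no peak was called in it in any of the 6 lists. Peak lists hold no expression, so they do not check the knockdown. The TET genes, which encode the enzymes that make 5hmC, all carried peaks. TET1 was covered over 5.33% ± 0.613 of its length in control and 5.84% ± 0.241 in knockdown libraries (SD, n = 3 each), TET2 over 3.51% ± 1.17 and 3.86% ± 0.590, and TET3 over 5.08% ± 0.428 and 5.21% ± 0.624. Adjusted p from limma was 0.466, 0.569 and 0.690, so none of the TET genes passed the test.

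In control cells, 5hmC peaks covered noradrenergic lineage genes far more than genes of the same length. The noradrenergic neuroblastoma markers had a median control coverage of 19.4%, above all of 10000 random lists of matched gene length, whose median was 1.78%. DBH, which makes noradrenaline, was covered over 36.8% ± 5.74 of its length in control and 41.3% ± 0.953 in knockdown libraries, TH, the tyrosine hydroxylase gene, over 45% ± 3.12 and 50.3% ± 6.82, and GATA3, a transcription factor of the lineage, over 23% ± 3.93 and 24% ± 3.84 (SD, n = 3 each). These 3 genes were chosen after their values were seen, and none passed the test between the groups (limma adjusted p = 0.486, 0.458 and 0.621). Splicing factors (8.20%, percentile 100 among the random lists), TDP-43 cryptic splicing targets (5.55%, percentile 99.6), Wnt genes (4.94%, percentile 99.2) and glial markers (6.24%, percentile 98.6) were also well covered. Embryonic kidney 293T markers (0.125%, percentile 1.53) and long synaptic genes (2.2%, percentile 3.73) were sparsely covered. Of 16814 protein-coding genes of at least 5 kb, 4648 had no peak in any list.

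**Figure D2:**
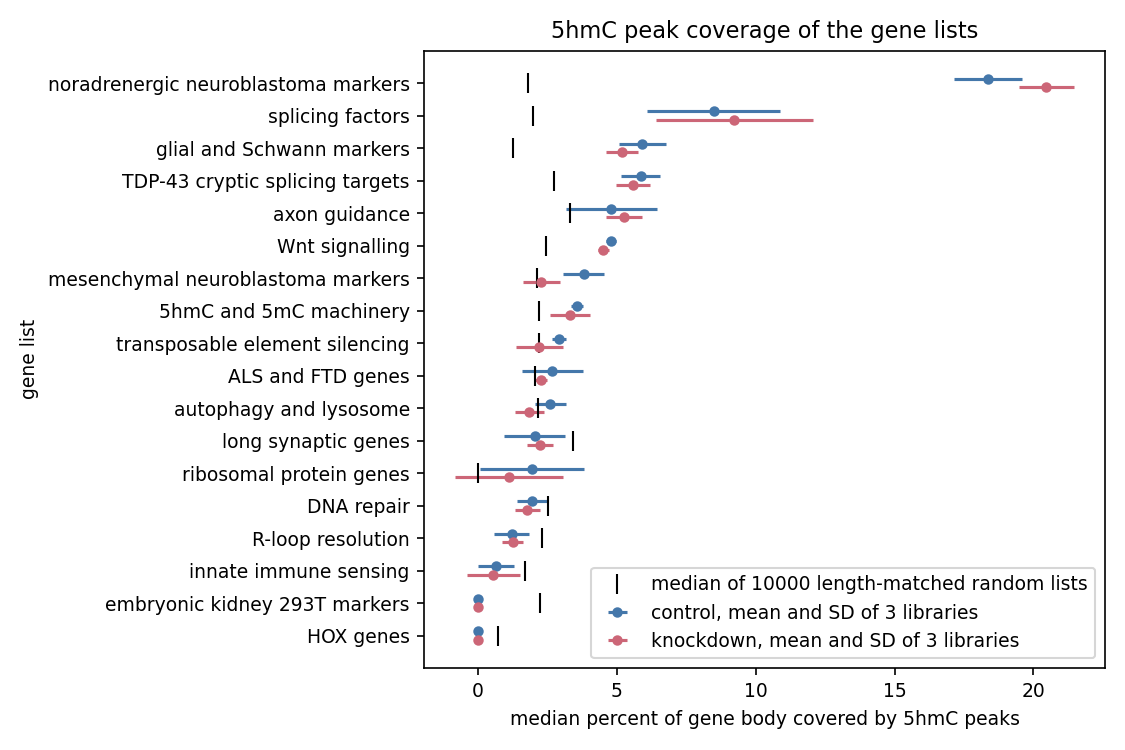
Median percent of the gene body covered by 5hmC peaks (x axis) in each of 18 gene lists (y axis), as mean and SD of the medians of 3 libraries per group, with black ticks for the median of 10000 random lists of matched gene length. Noradrenergic markers lie at 18.4% ± 1.22 in control and 20.5% ± 0.991 in knockdown libraries, against 1.78% in random lists. The ticks are another summary, the median over genes of their mean coverage in control libraries, which was 19.4% for these markers. Random lists were not computed for knockdown libraries.

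The number of peaks and the genome they covered differed between the groups by less than the spread between replicates. Control libraries had 134024 ± 20535 peaks and knockdown libraries 130946 ± 11402 (SD, n = 3 each, exact permutation p = 0.9). Peaks covered 92.3 ± 16.5 Mb in control and 88.8 ± 10.3 Mb in knockdown libraries (SD, n = 3 each, exact permutation p = 0.8). Median peak width was 529 ± 13.3 bp in control and 522 ± 13.4 bp in knockdown libraries. Without control 2, or without knockdown 2, the knockdown mean was the higher, by 8488 or 2485 peaks and by 5.87 or 1.74 Mb.

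Protein-coding genes held 58.9% ± 0.442 of peak summits in control and 59.4% ± 0.17 in knockdown libraries (SD, n = 3 each, exact permutation p = 0.1, adjusted p = 0.15). LncRNA genes, where they did not overlap protein-coding genes, held 11% ± 0.182 and 10.9% ± 0.0498 (exact permutation p = 0.8, adjusted p = 0.8). Outside both lay 30.1% ± 0.308 and 29.7% ± 0.137 (exact permutation p = 0.1, adjusted p = 0.15). The peak of largest −log10 p-value in every list lay on chromosome 3 near position 93470345, though in no list was its fold the largest. No regions were filtered out here as prone to artefacts. Of 23 chromosomes, 4 had shares of the covered bases that did not overlap between the groups, where chance gives 10% of them, or 2.3, and the highest other split of the libraries gave 10. Chromosome 2 held 9.51% ± 0.214 in control and 9.82% ± 0.0444 in knockdown libraries. Knockdown shares were the lower on chromosome 15 (3.46% ± 0.0998 and 3.27% ± 0.0517), chromosome 21 (1.09% ± 0.0154 and 1.02% ± 0.0155) and chromosome X (1.02% ± 0.0465 and 0.934% ± 0.0557). None passed the exact permutation test after adjustment (adjusted p = 0.575 for each), which 3 against 3 samples cannot pass. Without control 2, the groups did not overlap on 18 chromosomes, where chance gives 20% of them, or 4.6, for 2 against 3 libraries. Without any other single library they did not overlap on 4 to 6.

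Libraries of a group shared more of their peaks than libraries of different groups. The mean Jaccard index was 60.4% within and 56.0% between groups, a difference of 4.37 points (exact permutation p = 0.1, the smallest that 10 splits allow). The highest difference in any other split was 1.75 points. Not every pair followed the groups, since control 2 shared 62.2% with knockdown 1 and 56.2% with control 1.

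Single regions had peaks in every library of 1 group and in none of the other, among them regions in the glutamate receptor gene GRIN2A and the dopamine synthesis gene DDC. Of 200818 merged regions, 71364 had a peak in all 6 libraries, 3951 in the 3 controls alone and 2126 in the 3 knockdowns alone. The longest control-only regions lay in GRIN2A (chromosome 16, 10079651 to 10081812, 2162 bp), ATG13, an autophagy initiation factor (chromosome 11, 46648520 to 46650373, 1854 bp), and PAX5, a transcription factor (chromosome 9, 36878918 to 36880706, 1789 bp). The longest knockdown-only regions lay in DAPP1, a signalling adaptor (chromosome 4, 99847343 to 99849784, 2442 bp), DDC (chromosome 7, 50564179 to 50566188, 2010 bp), and BMPR1B, a bone morphogenetic protein receptor (chromosome 4, 94978987 to 94980973, 1987 bp). Each of these overlapped the span of its gene, and exon or intron was not assigned. Control-only regions had a median width of 509 bp and knockdown-only regions 518 bp, against 969 bp for regions found in all 6 libraries, which join peaks of more lists. Group-specific regions were also the weaker. The median of their smallest −log10 q-value was 6.17 (control-only) and 5.39 (knockdown-only), against 10.8 for regions in all 6. That value was at least 5 in 64.9%, 55.8% and 84.9% of them. Control-only regions made up 65.0% of the 6077 group-specific regions, and 54.5% (3298 against 2749) with equal numbers of peaks per list. Without control 2, the order turned, with 5228 control-only and 6740 knockdown-only regions, and control-only regions numbered 7198 without control 1, 6359 without control 3, 6453 without knockdown 1 and 6066 without knockdown 3. Knockdown-only regions numbered 3274, 4678 and 3678 without knockdowns 1, 2 and 3.

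**Figure D3:**
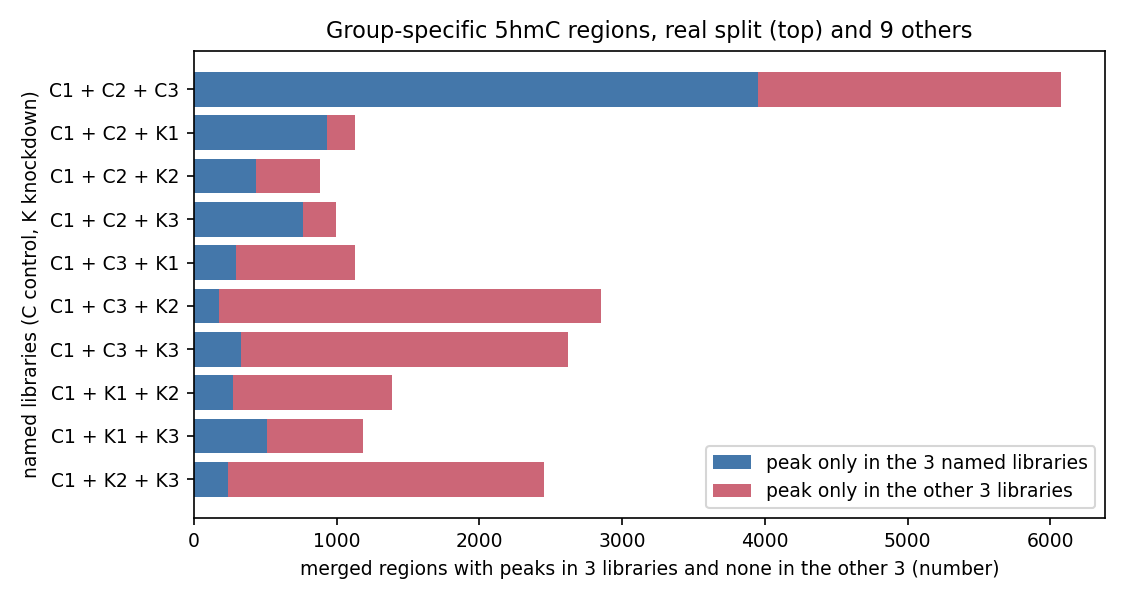
Number of merged regions with peaks in all 3 libraries on 1 side of a split and in none on the other, for the real split (top) and the 9 other splits of the 6 libraries, with C for control and K for knockdown. The real split has 6077 such regions, and the highest other split has 2853.

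Over gene bodies, peak coverage rose at CHGA, the chromogranin A gene of secretory granules, and fell at CRABP2, which encodes a retinoic acid-binding protein. CHGA (chromosome 14, 92922664 to 92935285) was covered over 15.7% ± 2.21 of its length in control and 47.0% ± 4.53 in knockdown libraries (SD, n = 3 each), a log2 difference of 1.63 (SE 0.12, limma adjusted p = 0.00468). CRABP2 (chromosome 1, 156699606 to 156705784) was covered over 36.6% ± 5.91 and 6.48% ± 0.470, a log2 difference of -2.22 (SE 0.10, limma adjusted p = 0.00210). Of 10077 genes tested, 18 rose and 51 fell in the knockdown libraries, and 1360 had an unadjusted p under 0.05. Simulations without planted changes gave 2 to 17 calls, so some of these calls may be false.

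Peaks were present in both groups at 6 of the genes that rose and 5 of those that fell, chosen for naming after their values were seen. Besides CHGA, coverage rose at ADH4, an alcohol dehydrogenase (3.39% ± 1.06 to 9.02% ± 0.433), HTR1E, a serotonin receptor (4.63% ± 1.33 to 11.5% ± 1.29), and KCNH1, a voltage-gated potassium channel (6.64% ± 1.05 to 11.7% ± 1.38). It also rose at TALDO1, the transaldolase of the pentose phosphate pathway (1.93% ± 0.220 to 4.93% ± 0.813), and ZNF789, a zinc finger gene (2.51% ± 0.325 to 5.84% ± 0.700). Besides CRABP2, coverage fell at PCARE, a photoreceptor cilium gene (31.7% ± 0.524 to 16.3% ± 1.61), KCNT1, a sodium-activated potassium channel (13.7% ± 1.38 to 4.77% ± 0.588), EML2, a microtubule-associated protein (6.81% ± 0.862 to 1.76% ± 0.503), and PXDC1 (8.16% ± 1.16 to 1.47% ± 0.366). All values are means ± SD of 3 libraries, and limma adjusted p for these 9 genes lay between 0.0105 for HTR1E and 0.0383 for PCARE. TALDO1 and PCARE were called under 7 of 17 alternatives and EML2 under 6, the others named here under 9 to 15. In peaks per 10 kb, the log2 difference of PCARE was -0.13 (limma adjusted p = 0.753, with 0.0109 to 0.753 over its alternatives).

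**Figure D4:**
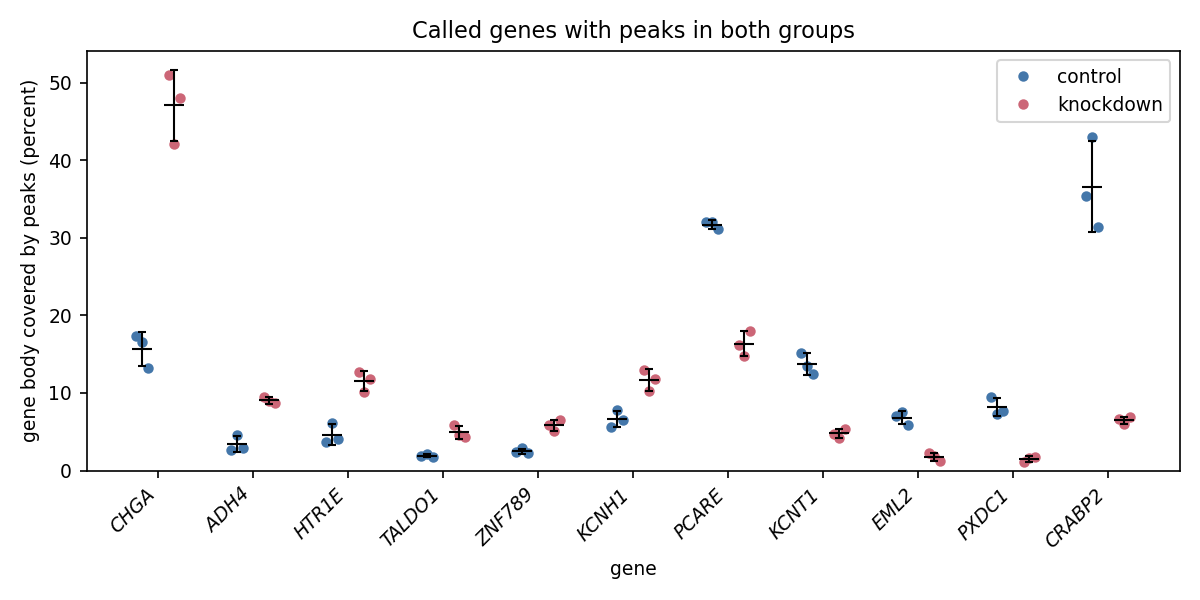
Percent of the gene body covered by 5hmC peaks (y axis) for the 11 called genes with peaks in both groups (x axis), with a point per library and black bars for the mean and SD of 3 libraries. CHGA lies at 47.0% in knockdown and 15.7% in control, and CRABP2 at 6.48% and 36.6%.

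The other called genes, 12 that rose and 46 that fell, had no peak called in any library of 1 group, so no fold is given. Among those with no peak in the control libraries, knockdown coverage was 5.70% ± 0.948 at HNRNPAB, which encodes an RNA-binding ribonucleoprotein, 6.98% ± 3.94 at RAG2, a recombinase subunit of lymphocytes, and 7.98% ± 2.30 at the uncharacterised LOC128966726. It was 5.35% ± 0.530 at GPR61, an orphan receptor, 5.62% ± 2.17 at SLC2A8, a glucose transporter, 5.00% ± 1.20 at PRRG2, 3.96% ± 0.849 at AIMP2 and 3.54% ± 0.179 at UBE2A, a ubiquitin-conjugating enzyme. SNX21, ATOSB, SCIMP and GBA2, a glucosylceramidase, lay between 2.86% and 3.39%. Among those with no peak in the knockdown libraries, control coverage was 12% ± 1.77 at ZC3H12A, an endoribonuclease gene, 11.8% ± 6.00 at RPS4X, a ribosomal protein gene, 11.5% ± 3.64 at TMEM238L and 11.8% ± 7.43 at CD37, a leukocyte tetraspanin. It was 9.92% ± 3.05 at EFNA3, an ephrin ligand, 9.88% ± 2.90 at IGFBP1, 9.71% ± 0.947 at C20orf204, 10.0% ± 3.09 at SPAG4 and 9.04% ± 0.953 at KCNK4, a potassium channel. TIMP4, SLAMF8 and ODAM lay between 7.5% and 7.66%. All are means ± SD of 3 libraries, and the limma adjusted p of these 24 genes was at most 0.0269 for SCIMP. In each gene, the libraries of 1 group all had a coverage of 0, so the spread of 5hmC in that group is not measured. These p-values therefore rest on a step between called and not called. AIMP2, SNX21, ATOSB, SCIMP and GBA2 had no value at the stricter peak threshold or with equal numbers of peaks. The genes that rose had a median length of 12314 bp and those that fell 9928 bp, against 45742 bp for all tested genes.

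Counts of called genes moved with single libraries: 5 rose and 10 fell without control 3, 40 rose and 85 fell without control 2, 28 rose without control 1 and 9 rose without knockdown 3. Without centring, 13 rose and 95 fell, so that 88.0% of calls were lower in place of 73.9%, and among other settings the counts moved by over 1.5 times to 97 lower at the stricter peak threshold, 102 lower in peaks per 10 kb and 30 higher with equal numbers of peaks. The centring removed a median shift of -0.10 on the log2 scale between knockdown and control libraries, so all differences are relative to it.

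In 100-kb windows, coverage rose in windows over BMPR1B, HTR1E, SMOC1 and KCNH1 and fell over MBP, KCNT1, PXDC1, ARHGEF28, CRISPLD2, ISLR2 and RBFOX3. The window in BMPR1B (chromosome 4, 94900001 to 95000000) was covered over 3.25% ± 1.39 in control and 9.82% ± 0.701 in knockdown libraries (SD, n = 3 each, log2 difference 1.43, SE 0.16, limma adjusted p = 0.0155). The window over MBP, the myelin basic protein gene (chromosome 18, 77100001 to 77200000), was covered over 6.60% ± 1.11 and 1.80% ± 0.735 (log2 difference -1.43, SE 0.18, limma adjusted p = 0.0179). The window over RBFOX3, the gene of the neuronal antigen NeuN (chromosome 17, 79100001 to 79200000), was covered over 10.2% ± 1.55 and 3.88% ± 0.135 (log2 difference -1.15, SE 0.18, limma adjusted p = 0.0436). The window over SMOC1 (chromosome 14, 69900001 to 70000000) had no peak in the control libraries and was covered over 2.26% ± 0.0456 in the knockdown libraries. The window over KCNT1 and SOHLH1 (chromosome 9, 135700001 to 135800000) had 13.9% ± 1.52 and 5.30% ± 0.504, and that over ISLR2, ISLR and STRA6 (chromosome 15, 74100001 to 74200000) had 19.2% ± 1.79 and 9.27% ± 0.686 (limma adjusted p = 0.0179 and 0.0398). In all, 5 windows rose and 9 fell of 17510 tested, 3 of them without a protein-coding gene, and 2838 had an unadjusted p under 0.05 in limma. In limma no window was called without control 3 or any single knockdown library (1714 to 1973 with an unadjusted p under 0.05), without centring (1848) or at 1 Mb (340 of 2140), and the counts rose to 92 and 73 without control 1, 1023 and 858 without control 2, and 87 and 124 with quantile normalization. The counts also moved to 2 and 2 or 15 and 19 at pseudocounts of 0.25 and 4, to 16 and 38 at the stricter threshold, to 10 and 23 without the filter, and to 9 higher with equal numbers of peaks.

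Splicing factors and long synaptic genes were the gene lists called higher in the knockdown libraries by camera at its preset correlation. Of 35 measured splicing factors, 26 had a positive and 9 a negative log2 difference, and of 25 long synaptic genes 21 and 4 (camera adjusted p = 0.0235 for both, from limma). Neither call held with an estimated correlation (adjusted p = 0.761 with an estimated correlation for both, and for no list under 0.761), and fry's directional test gave an adjusted p of 0.449 for both. These differences are relative to the centring: before it, and with sparsely covered members included, the median over long synaptic genes of their mean coverage was 2.2% in control and 2.01% in knockdown libraries, while the libraries' own medians averaged 2.05% ± 1.1 and 2.24% ± 0.463 (SD, n = 3 each), so the uncentred direction depends on the summary. No member of either list passed the test over all genes or adjusted over the list alone. Among splicing factors, TIAL1 was covered over 2.22% ± 1.30 in control and 5.03% ± 1.63 in knockdown libraries, HNRNPD over 12.2% ± 5.72 and 20.2% ± 2.61, and SRSF7 over 23.8% ± 11.1 and 39.5% ± 8.06, while HNRNPL had 8.56% ± 1.83 and 4.17% ± 1.37 (SD, n = 3 each). Among synaptic genes, the cell adhesion gene CNTN4 had 5.97% ± 2.01 and 7.52% ± 0.631, and the calcium channel subunit CACNA2D1 12.7% ± 6.47 and 16.8% ± 3.21. Both calls ended without control 1 (adjusted p = 0.296 for synaptic genes and 0.289 for splicing factors) and without knockdown 1 (0.196 for both). The call of splicing factors also ended at the stricter peak threshold (0.0543) and with quantile normalization (0.0724), and that of synaptic genes once a trend with gene density and length was removed, a correction chosen after seeing the data (0.963). Over these and the other alternatives run with the preset correlation, the adjusted p ran from 0.000237 to 0.963 for synaptic genes and from 0.00112 to 0.289 for splicing factors. Called lists numbered 4 without control 2 and without knockdown 2.

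Among 20 measured noradrenergic neuroblastoma markers, CHGA rose, and adjusted over the list alone the noradrenaline transporter gene SLC6A2 and the receptor tyrosine kinase gene RET fell. SLC6A2 was covered over 11.1% ± 0.964 in control and 4.88% ± 1.42 in knockdown libraries, and RET over 40.9% ± 2.32 and 24.2% ± 1.19 (SD, n = 3 each, limma adjusted p = 0.00987 over the list and 0.0901 and 0.0981 over all genes). RET had no such difference in peaks per 10 kb, where its log2 difference was 0.040. DDC had 21.5% ± 1.28 and 25.7% ± 0.253 (limma adjusted p = 0.0531 over the list). The list as a set gave a camera adjusted p of 0.189, with 14 members of positive and 6 of negative sign. Fry's mixed test, which asks whether the genes of a set change in either direction and compares it with no other genes, gave an adjusted p of 5.50e-05, and its directional test 0.224.

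The myelin genes MBP and PMP22 fell among markers of other cell types. Of 10 glial and Schwann markers, MBP (10.9% ± 0.616 in control, 5.20% ± 0.586 in knockdown) and PMP22 (4.35% ± 1.35 and 1.77% ± 0.0894) fell adjusted over the list alone (SD, n = 3 each, limma adjusted p = 0.00496 and 0.0144) and none over all genes, with a camera adjusted p of 0.314. Of 3 measured markers of embryonic kidney 293T cells, EYA1 rose adjusted over the list alone (5.96% ± 1.95 and 8.49% ± 1.33, limma adjusted p = 0.0307, with overlapping groups) and none over all genes (camera adjusted p = 0.243). Mesenchymal neuroblastoma markers had 8 positive and 11 negative members of 19 and no call over all genes or adjusted over the list alone (camera adjusted p = 0.527), with COL6A3 at 10.2% ± 0.560 and 13.2% ± 0.871 and NOTCH3 at 6.68% ± 0.505 and 3.45% ± 1.52.

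Among ribosomal protein genes, RPS4X fell over all genes, and RPL24 rose adjusted over the list alone (6.89% ± 0.955 in control and 8.93% ± 0.738 in knockdown, SD, n = 3 each, limma adjusted p = 0.0363). Over the alternatives, the log2 difference of RPL24 went down to 0.076 (limma adjusted p over all genes 0.0760 to 0.821). Among 22 DNA repair genes, the polymerase gene POLM fell adjusted over the list alone (9.81% ± 2.27 and 1.02% ± 1.76, limma adjusted p = 0.0426) and none over all genes. In the lists that follow, no member passed over all genes or adjusted over the list alone, except those just named.

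Genes of the 5hmC and 5mC machinery, TDP-43 targets and R-loop factors were not called as lists by camera (fry's mixed test is given below). For 16 genes of the 5hmC and 5mC machinery the camera adjusted p was 0.850, with the glycosylase gene SMUG1 at 14.7% ± 1.85 in control and 10.1% ± 2.41 in knockdown libraries (SD, n = 3 each, here and below). For 24 TDP-43 cryptic splicing targets it was 0.850, with the synaptotagmin gene SYT7 at 24.7% ± 4.12 and 13.8% ± 1.45 and ICA1 at 13.6% ± 3.43 and 17.3% ± 1.38. For 11 R-loop genes it was 0.220, 10 of them positive, with the helicase gene DDX39B at 2.97% ± 0.298 and 5.69% ± 2.19 and the topoisomerase gene TOP1 at 8.43% ± 3.19 and 9.32% ± 2.15. For 18 ALS and FTD genes it was 0.527, with VAPB at 9.51% ± 2.42 and 13% ± 1.37 and ANXA11 at 8.93% ± 0.358 and 5.85% ± 0.472. The R-loop list was called under 2 of its alternatives (adjusted p 0.0408 to 0.821 over all alternatives).

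Developmental signalling lists were not called by camera either. For 28 axon guidance genes the camera adjusted p was 0.0717, 22 of them positive, with the ephrin gene EFNA5 at 16.1% ± 5.18 in control and 21.8% ± 2.71 in knockdown libraries and the netrin receptor gene UNC5C at 14.7% ± 6.02 and 21.2% ± 3.65. That list was called under 4 of its alternatives (adjusted p 0.0122 to 0.978 over all alternatives). For 26 Wnt genes it was 0.189, with the coreceptor gene LRP6 at 5.90% ± 1.52 and 8.50% ± 0.808 and the ligand gene WNT7B at 4.77% ± 0.564 and 2.22% ± 0.486. For 5 HOX genes it was 0.388, with HOXC6 at 21.3% ± 1.01 and 26.6% ± 3.13.

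Stress and silencing lists likewise were not called by camera. For 21 autophagy and lysosome genes the camera adjusted p was 0.314, with ATG13 at 2.5% ± 1.02 in control and 0.256% ± 0.443 in knockdown libraries and ULK2, a kinase of autophagy initiation, at 3.27% ± 0.550 and 1.98% ± 0.539. For 19 transposable element silencing genes it was 0.850, with MORC2 at 3.19% ± 0.112 and 1.46% ± 0.328 and the RNA editing gene ADAR at 7.37% ± 0.540 and 5.13% ± 1.44. For 15 innate immune genes it was 0.850, with the DNA sensor gene CGAS at 2.10% ± 1.36 in control and no peak called in knockdown libraries, and OAS2 at 2.49% ± 0.731 and 3.89% ± 0.599. For 22 DNA repair genes it was 0.765 and for 15 ribosomal protein genes 0.766. Fry's mixed test gave an adjusted p of 0.000176 for the glial, 0.000506 for the ribosomal protein, 0.00685 for the 5hmC and 5mC machinery, 0.00766 for the mesenchymal and the autophagy, and 0.0166 for the Wnt list. Median, mean and camera disagreed in sign for DNA repair (median 0.093, mean -0.057, camera up), innate immune sensing (0.041, -0.077, up), transposable element silencing (0.017, 0.0041, down) and ribosomal protein genes (0.080, -0.33, down), all on the log2 scale.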

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

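All alternatives were planned except the gene density and length correction and those of the implied background, chosen after seeing the data. Where no cause is named, the cause was not tested. The difference in peaks per library ranged from -11116 to 8488 with a library left out, and in covered genome from -9.34 to 5.87 Mb, turning positive without control 2 or knockdown 2. The overlap difference kept its sign throughout (3.26 to 6.00 points), as did the protein-coding share of summits (0.219 to 0.634 points). Chromosomes with groups that did not overlap numbered 4 to 18 with a library left out, 18 being without control 2, where chance gives 4.6 for 2 against 3.

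With a library left out, control-only regions ranged from 5109 to 7198 and knockdown-only regions from 2638 to 6740. Fewer libraries then had to agree, which does not account for the spread between the libraries left out. Knockdown-only regions numbered 6740 without control 2, against 2802 without control 1 and 2638 without control 3. Genes that rose ranged from 5 to 40 and genes that fell from 10 to 85. Windows that rose ranged from 0 to 1023 and windows that fell from 0 to 858, with 1714 to 5044 at an unadjusted p under 0.05 in limma. Called lists ranged from 0 to 4.

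With equal numbers of peaks, 30 genes and 9 windows rose. At the stricter threshold 97 genes fell, and 16 windows rose and 38 fell. Without centring 95 genes fell, and 0 windows were called in limma (1848 with an unadjusted p under 0.05). In peaks per 10 kb 102 genes fell. At a pseudocount of 0.25, 2 windows rose and 2 fell, and at 4, 15 rose and 19 fell. Without the filter 10 rose and 23 fell. With quantile normalization 87 rose and 124 fell, and 1 list was called. At 1 Mb 0 were called, with 340 of 2140 at an unadjusted p under 0.05 and fewer windows tested. With an estimated correlation 0 lists were called, and with the density and length correction 1.

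The labels do not say whether replicate numbers pair the samples. Same-numbered libraries had correlations of deviations of -0.125, -0.0817 and -0.0143 over genes, and no library correlated best with its own number. These values gave no sign of pairing, but with 3 libraries per group they cannot exclude it. With the replicate block, 0 genes and 0 windows were called in limma (1052 genes and 2125 windows with an unadjusted p under 0.05), with 2 residual degrees of freedom in place of 4. Called lists stayed at 2 under the replicate block, and the difference in peaks stayed at -3078.

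Of 35 named genes that were called, none changed sign, which most could hardly do, having no peak in 1 group. With a library left out, 11 (without control 3) to 32 (without control 2) were still called, with 23, 19 and 18 without knockdowns 1, 2 and 3. At the stricter threshold and with equal numbers of peaks 18 of the 30 with a value were, in peaks per 10 kb 27 of 35, and under the replicate block 0. The implied background ratio ranged from 0.405 to 0.771 with a library left out. Of 71 that were not called, 6 changed sign: MBD1 at the stricter threshold (-0.43) and with equal numbers of peaks (-0.39), CDH6 in peaks per 10 kb (0.076) and with a library left out (-0.19 to 0.030, the highest without knockdown 2), and in peaks per 10 kb CTSB (0.24), HOXD11 (0.076), HOXC4 (-0.039) and RET (0.040). Promoter peaks, promoter and exon features with their alternatives, and repeat and CpG content were not run. Depth is known only as an implied background, and it limits which weak peaks could be called.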

Other observations

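The tests on gene density and length, number of peaks, depth and other splits were chosen after the results were seen, and the one on neighbouring genes before. Some long genes held many group-specific regions, and those with most were chosen after their values were seen, with no test of enrichment. NRG1, which encodes neuregulin, held 13 control-only regions of its 151, GSE1 10 of 168, PTPRN2 9 of 159 and SHANK2, a postsynaptic scaffold gene, 7 of 95. BMPR1B held 9 knockdown-only regions of 98, KCNH1 8 of 83, LRMDA 8 of 154, KCNMA1 7 of 148, RYR2, a calcium release channel gene, 7 of 132 and TENM3 6 of 241. KCNH1 also rose over its whole body, and BMPR1B in a 100-kb window.

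The called gene bodies may reflect the knockdown, the lines or the libraries. As to a copy-number difference between the stable lines over 1 Mb, tested genes starting within 1 Mb of a called gene moved by a median of 0.082 in its direction (log2, 95% bootstrap interval 0.039 to 0.12). The called genes moved by a median of 2.42, a value set by genes without a peak in 1 group. How far peak coverage follows copy number was not tested, so copy number is not excluded. After a trend with gene density and length was removed, 66 of the 69 calls were kept. Removing a smooth trend could hardly end calls of genes without a peak in 1 group, so this does not decide on that trend. Called genes lay in gene-dense places, with a median of 20.5 (rose) and 21 (fell) protein-coding genes within 500 kb. All tested genes had a median of 10. With equal numbers of peaks per list, 69.7% of 99 called genes were lower (exact binomial interval 59.6 to 78.5, taking genes as independent), which goes against the number of called peaks as the whole cause of the excess of lower calls, though 37 of the 69 genes called with all peaks were among the 99 and 47.1% of called windows were lower. A lower depth of the knockdown libraries, which was not measured directly, stays open for those genes and cannot be told apart from the knockdown. Their implied background, an uncertain measure of depth, lay below every control, at 0.488 times the control mean (0.771 without control 2, 0.610 without rescaling its values).

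The group-specific regions were weighed next. With equal numbers of peaks per list the control-only share fell to 54.5%, so the excess of control-only regions may come from the number of peaks called. Knockdown-only regions then numbered 2749, against at most 1475 on a side of any other split, but with all peaks they numbered 2126, below the 2679 of another split. Equal numbers of peaks do not equalise depth, so the depth of the knockdown libraries cannot be told apart from the knockdown for these regions, and both stay open.

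Once a trend of each library with gene density and length was removed, the mean log2 difference of long synaptic genes went from 0.25 ± 0.21 (SD over 25 genes) to 0.040 ± 0.21. The call ended because the difference shrank (camera adjusted p = 0.963). The list is one of long genes, and the correction would also remove a group difference shared by long genes. It therefore cannot tell such a trend from a change at long genes. Splicing factors went from 0.29 ± 0.52 to 0.34 ± 0.53 over 35 genes and were still called (camera adjusted p = 0.0117), which goes against that trend as the cause. The estimated correlation leaves both open.

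The 10 splits of 6 libraries are too few for a share under 0.05. The real split called 69 genes and the highest other 10, so that 1 split, the real one itself, reached that number. For windows the numbers were 14 and 0, and for group-specific regions 6077 and 2853, again reached by the real split alone. The real split called 2 gene lists and the highest other 5, with 3 splits at 2 or more, the real one included. The splits with 4 and 5 called lists joined controls 1 and 3 with knockdown 2 or 3, so list calls also arose from splits other than the groups.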
